A study of Homo sapiens and Mus musculus with 36 samples.

How the data were processed

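Bulk ATAC-seq libraries of pancreatic islets were analysed from 2 deposited tables, 1 for mouse and 1 for human. Per the labels, islets were synchronized with forskolin, and libraries were made with an Omni-ATAC protocol and Nextera Tn5 enzyme. The submitters' processing notes name Bowtie2, HOMER, DESeq2, R 4.1.0, STAR, RSEM, Cell Ranger, Seurat and Signac and the builds mm10 and hg38, without saying which served which step. The aligner settings, read shifting for Tn5, duplicate removal and peak calling are not given in the sources used here. A shift of a few bases would hardly move counts over whole peaks, while duplicates and peak calling can change them.

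The mouse table held 1 column per library of normalized counts, a signal the authors scaled per library, beside a deposited adjusted p-value. From the values, each column of 10 libraries was a set of whole reads times 1 factor per library. In these columns 100% of values came within 0.02 reads of a whole number, and the recovered reads per library are the depths given in the results. For mutant 36 h replicate 2 and mutant 48 h replicate 2 the values were also multiples of a step, but a check of the unit did not accept the step, so their depth is not given. The depth comparison and all count tests therefore leave out 2 of the 6 mutant libraries. The authors' deposited adjusted p-value has no named comparison in the file header. It was under 0.05 for 1207 of 46236 peaks and was used only for a comparison with the tests made here.

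The human table was the authors' output of eJTK, a rank test that compares a time course with reference waveforms. Per the file headers it gave for each peak a p-value, an empirical p-value, a p-value from a gamma fit and its adjusted p-value, Kendall's tau as a score, and the phase of the best waveform in hours. The column of the gamma p-value was used throughout. Of its 246 values under 0.001, 45 equalled the p-value corrected for the number of waveforms tried, so not all came from a gamma fit. Counts from this column are therefore set against uniform p-values only as a rough guide. The summary scores in the deposited table were z-scores, since all 144673 peaks had a mean of 0 and the same SD, each within 1e-6, and it held no value per library. The planned model of each peak with donor and 24 h terms was therefore not run, nor was any setting that needs values per library. Depth of the human libraries is unknown here. All human p-values are the authors'.

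Samples were grouped from the titles, by genotype and time in mouse and by time in human. The main mouse test was limma 3.58.1 in R 4.3.3 on log2 of the deposited normalized count plus 1, which understates changes of low peaks. Peaks with a mean of at least 10 over the 12 libraries were kept, 42889 of them. The 4 groups were fitted together with 8 residual degrees of freedom and empirical Bayes moderation with an intensity trend, and p-values were two-sided and Benjamini-Hochberg adjusted with a threshold of 0.05. The 6 contrasts were genotype over both times, genotype at each time, time in each genotype, and their interaction. No block was used for the replicate numbers, so the genotype fit takes heterozygote libraries that may be paired as separate samples. The numbers were checked by correlating deviations from group means between libraries with the same number. In the comparison of times in heterozygotes these were 0.149, 0.110 and 0.187, all over 0.1, so the numbers were treated as pairing there. In the other comparisons at least 1 of the 3 fell below that. Single values there still reached 0.201 (heterozygotes and mutants at 48 h) and 0.173 (mutants over time), so this sign of pairing is weak.

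The test was checked on simulated reads for the 42889 peaks with 200 of them changed. For genotype over both times 11.9% of 1.5-fold, 70.1% of 2-fold and 100% of 4-fold changes were recovered, with 0 false calls among 121. For genotype at 36 h the shares were 2.99%, 22.4% and 97.0% with 1 false call among 82, and for time in heterozygotes 4.48%, 32.8% and 95.5% with 7 among 95. In the simulation, changes under 2-fold within 1 time were thus mostly missed. The simulated peaks were independent, with 1 common spread and no effect shared within a library or a replicate number. The real libraries differ from that, so these shares and false calls need not hold for them.

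The mouse and human tests, the gene lists and the rule for naming peaks were fixed before the data were examined. The rule takes the 10 largest changes in each direction with an adjusted p under 0.05, a mean of at least 20 and no overlap between groups, or the 5 smallest p-values where fewer than 10 peaks pass. For human peaks, of which none passed, it takes the 10 smallest p-values. Single peaks of list genes were named after their values were seen, and some are not reported here. Because the mouse files do not pair identifiers with genes, at most 2 identifiers per direction and comparison are printed, and the planned mouse gene lists, motif tests and Pdx1 peaks were not run. GC content was not checked either.

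Human peaks were assigned to the protein-coding gene they overlap or lie nearest to, within 100 kb, from gene intervals of GRCh38.p14. This replaced the planned distance to a transcription start, because the table used gives no strand. The build was checked by the share of gene ends inside a peak, 35.7%, against 5.78% after a shift of 100000 bp. Of 20056 genes, those of 17 lists were tested. Since no peak passed the adjusted threshold, the share of list peaks with an unadjusted p under 0.05 was compared with 10000 random peak sets matched on 10 equal parts of the table, two-sided, and adjusted over the lists. That test was chosen after the data were seen. On simulated lists it called 2 of 40 without an effect and 40 of 40 with a planted one, over 144000 simulated peaks. The size of the simulated lists and of the planted effect is not given here. Real lists held 30 to 526 peaks, often several at 1 gene, so these shares need not hold for them. The Y chromosome was left out of lists and named peaks.

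Alternatives covered the pseudocount (0.5 and 5), the filter (none and a mean of at least 50), median ratio, quantile and cyclic loess scaling, no intensity trend, a replicate block, fits on the compared groups alone, each library left out, a threshold of 0.10, and count tests with edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads of 10 libraries. DESeq2 left 1664 adjusted p-values of the genotype test undefined. Tables and figures were made with Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.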

Results

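Chromatin accessibility was measured by bulk ATAC-seq, which reads where the Tn5 transposase can insert adapters into open DNA, in cultured pancreatic islets of mice and of human donors. Islets were synchronized by a 1 h pulse of 10 µM forskolin, which raises cAMP, and collected at set hours afterwards. The mouse part held 12 libraries in 4 groups of 3, from islets labelled Pdx1 heterozygote and Pdx1A4 mutant at 36 and at 48 h. Pdx1 is a transcription factor that pancreas development and insulin-producing beta cells need. The human part held 24 libraries, from islets of 4 donors at 6 times between 24 and 44 h, and was analysed from the authors' deposited table of a rhythm test. The labels do not say whether the 3 mouse replicates of a group came from separate animals, so their p-values measure the spread between these samples, which may be technical.

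The mouse table listed 46236 peaks, of which 42889 had a mean normalized read count of at least 10 and were tested. Whole reads were recovered for 10 of the 12 libraries, with between 513207 reads in the listed peaks in heterozygote 48 h replicate 2 and 1930737 in mutant 36 h replicate 3. Heterozygote libraries held 1077060 ± 386916 reads (SD, n = 6) and mutant libraries 1609517 ± 412541 (SD, n = 4), a difference that missed the threshold of 0.05 (two-sided exact permutation test, p = 0.0667). That test leaves out 2 of the 6 mutant libraries, so it does not show that the genotypes had equal depth. The top 1% of peaks took 4.94% ± 0.0673 (SD, n = 6) of the signal in heterozygotes and 4.72% ± 0.176 (SD, n = 6) in mutants (two-sided exact permutation test over libraries, p = 0.0195). Averaged over both times of a replicate number, the same difference had an exact permutation p of 0.1, the smallest that 3 against 3 allows. On the log2 scale, libraries of 1 group correlated across peaks with Pearson's r between 0.722 and 0.904, and libraries of different groups with r between 0.670 and 0.885. Peaks at Pdx1 itself were not analysed here, because the mouse identifiers give a chromosome and a number without coordinates. For the same reason no mouse peak was tied to a gene.

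The first comparison asked which peaks differed between mutant and heterozygote islets over both times. In mutants 288 peaks were lower and 145 were higher (limma, Benjamini-Hochberg adjusted p threshold 0.05). An unadjusted p under 0.05 was found at 5555 peaks, where 2144 were expected by chance if peaks vary independently. Peaks can move together within a library, so here and below 2144 is a rough guide. False splits of the heterozygote libraries by time gave 3071, 1840 and 2368 such peaks, beside 3276 for the real one. The genotype fit takes each library as its own sample, although replicate numbers may pair the heterozygote ones. With both times of a number averaged, 3 against 3, limma called 196 peaks, 136 lower and 60 higher, of which 187 were among the 433, and with the replicate number as a block it called 703. The lower peaks fell by a median of 1.15 on the log2 scale, a 2.22-fold change with a median SE of 0.246. The higher peaks rose by a median of 1.00, or 2.00-fold, with a median SE of 0.219. Changed peaks were of typical signal, with median normalized counts of 20.1 for the lower and 20.5 for the higher ones and 20.2 for all tested peaks. Peak chr9-993 on chromosome 9 fell from 43.6 ± 24.9 to 13.9 ± 6.63 normalized reads at 36 h and from 73.4 ± 17.7 to 16.5 ± 9.85 at 48 h (SD, n = 3 each), a log2 change of -1.90 (SE 0.281, limma adjusted p = 0.00404). Peak chr11-1738 on chromosome 11 fell by 1.55 on the log2 scale (SE 0.301, limma adjusted p = 0.0155). Among the higher peaks, chr3-133 on chromosome 3 rose from 45.6 ± 17.6 to 89.9 ± 9.46 at 36 h and from 33.8 ± 8.93 to 66.1 ± 5.56 at 48 h (SD, n = 3 each), a log2 change of 1.01 (SE 0.167, limma adjusted p = 0.0071). Peak chr1-1152 on chromosome 1 rose by 1.01 (SE 0.220, limma adjusted p = 0.0270). In each of these 4 peaks the 6 mutant values lay apart from the 6 heterozygote values, which the rule for naming peaks required, and the same held for 40 of the 145 higher and 85 of the 288 lower peaks.

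**Figure D1:**
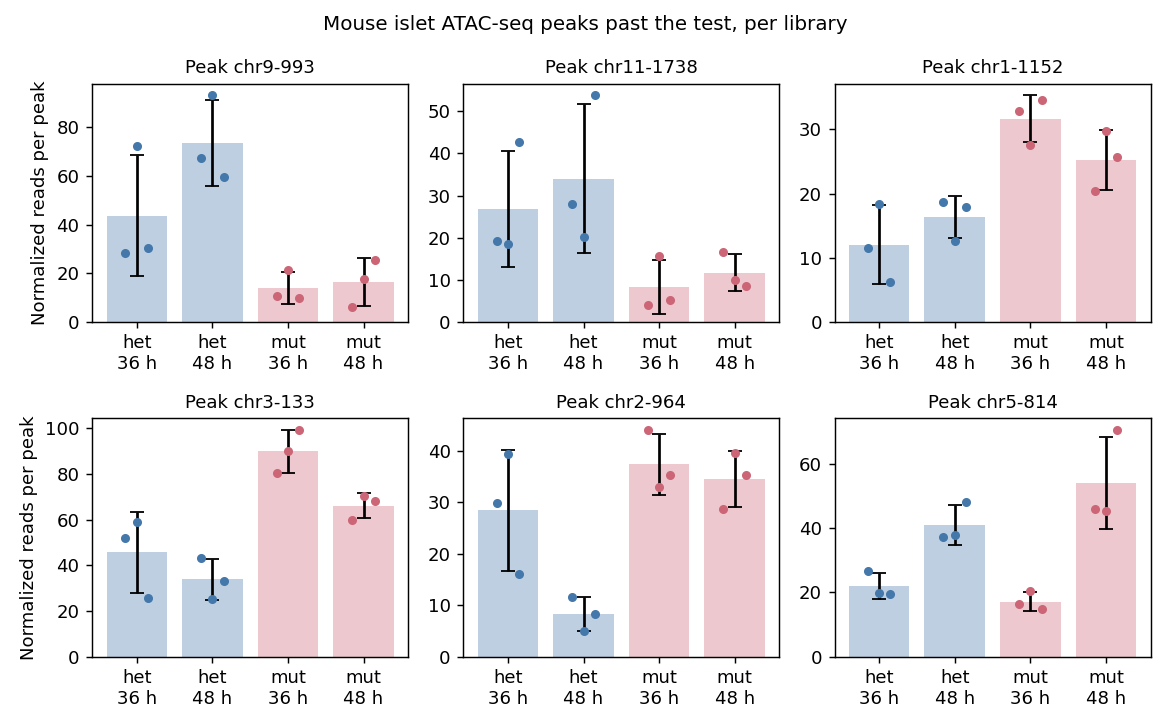
Normalized reads per peak (vertical axis) in heterozygote (het) and mutant (mut) islets at 36 and 48 h for 6 peaks that passed a test, with points for libraries, bars for means of 3 and error bars of 1 SD. Peak chr9-993 fell from 73.4 to 16.5 at 48 h, and chr5-814 rose from 17.2 at 36 h to 54.1 at 48 h in mutants.

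The number of genotype calls moved by over 1.5 times with 11 of the 12 libraries left out in turn, and with the model. On a scale from the heterozygote mean (0) to the mutant mean (1) of peaks called without it, heterozygote 36 h replicate 2 lay at 0.886. With both replicate 2 libraries at 36 h left out, 664 peaks were lower and 288 higher, 952 in all, and 389 of these were among the 433. Leaving out a heterozygote library gave 145, 1026 and 54 calls for replicates 1, 2 and 3 at 36 h, and 783, 683 and 232 for those at 48 h. The excess of lower peaks was not kept without heterozygote 48 h replicate 3, where 126 were higher and 106 lower. Leaving out a mutant library gave 85 and 68 calls for replicates 1 and 3 at 36 h, and 223, 64 and 225 for replicates 1, 2 and 3 at 48 h. The limma fit without an intensity trend called 0 peaks, and so did the fit with the share of signal in the top 1% of peaks as a covariate. On recovered reads of 10 libraries, edgeR called 731 peaks, 532 lower and 199 higher, and DESeq2 called 195, 176 lower and 19 higher, while limma on the same 10 libraries called 129.

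By chromosome, the lower peaks were spread over the genome except on the unplaced sequence JH584304, where 9 of 13 tested peaks were lower against 0.0873 expected (two-sided Fisher's exact test, adjusted p = 3.8e-16 over 22 sequences). Fisher's test takes peaks as independent. Peaks of 1 sequence can move together within a library, so its p does not measure the spread between samples. The median of those 9 peaks was 18.4 ± 9.16 normalized reads in heterozygotes and 7.17 ± 1.58 in mutants at 36 h (SD, n = 3 each), and 32.7 ± 5.09 and 12.5 ± 10.4 at 48 h (SD, n = 3 each). At 48 h the mutant spread came from replicate 3, at 24.4 beside 6.05 and 6.92 in replicates 1 and 2. No other chromosome passed this test in either direction. On chromosome 5, which carries Pdx1 in the mouse, 24 peaks were lower and 9 higher of 2712 tested, against 18.2 lower ones expected (adjusted p = 0.564). Of the 9 lower peaks with a log2 change of -2 or less, 4 lay on chromosome 5, a count made after these losses were noticed.

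At 36 h alone no peak passed for genotype with limma, with 2648 peaks at an unadjusted p under 0.05 and 2144 expected. Peak chr12-580 on chromosome 12 had the smallest p, with 39.1 ± 14.9 normalized reads in heterozygotes and 11.7 ± 2.95 in mutants (SD, n = 3 each, limma adjusted p = 0.156). On the recovered reads edgeR called 337 peaks at 36 h and DESeq2 30, and limma on the same 10 libraries called 10. Leaving out heterozygote 36 h replicate 2 gave 11 limma calls, leaving out mutant 36 h replicate 2 gave 15, and without both there were 84, 77 lower and 7 higher. With library quality weights limma called 412.

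At 48 h 4 peaks were lower in mutants and 1 was higher, and the 4 lower ones all lay on chromosome 5. Peak chr5-2089 fell from 32.3 ± 11 to 1.65 ± 0.735 normalized reads (SD, n = 3 each), a log2 change of -3.63 (SE 0.528, limma adjusted p = 0.0105). Peak chr5-1874 fell from 35.8 ± 17.1 to 2.05 ± 1.15 (SD, n = 3 each), a log2 change of -3.58 (SE 0.527, limma adjusted p = 0.0105). The higher peak, chr2-964 on chromosome 2, stood at 34.6 ± 5.45 in mutants and 8.32 ± 3.29 in heterozygotes (SD, n = 3 each), a log2 change of 1.98 (SE 0.309, limma adjusted p = 0.0139). With the replicate number as a block, limma called 82 peaks, edgeR on recovered reads called 4 and DESeq2 2. No peak passed at 48 h with limma without the intensity trend, with the covariate of signal in the top 1% of peaks, or among peaks with a mean of at least 50. Leaving out 1 library gave 38 and 14 calls for heterozygote 36 h replicates 2 and 3, 192, 11 and 15 for heterozygote 48 h replicates 1, 2 and 3, 9 for mutant 36 h replicate 2, and 2, 0 and 30 for mutant 48 h replicates 1, 2 and 3. The direction turned without a heterozygote 48 h library, with 115 higher and 77 lower without replicate 1, 6 and 5 without replicate 2, and 11 and 4 without replicate 3. Without both replicate 2 libraries at 36 h there were 15 calls. The 36 and 48 h comparisons used separate libraries, though replicate numbers may pair the heterozygote ones. The log2 changes of the 36 and 48 h comparisons correlated across peaks with r = 0.388. Of 297 peaks with p under 0.001 at 48 h, 273 had the same sign at 36 h, or 91.9%. These values are across peaks, which are not independent replicates.

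**Figure D2:**
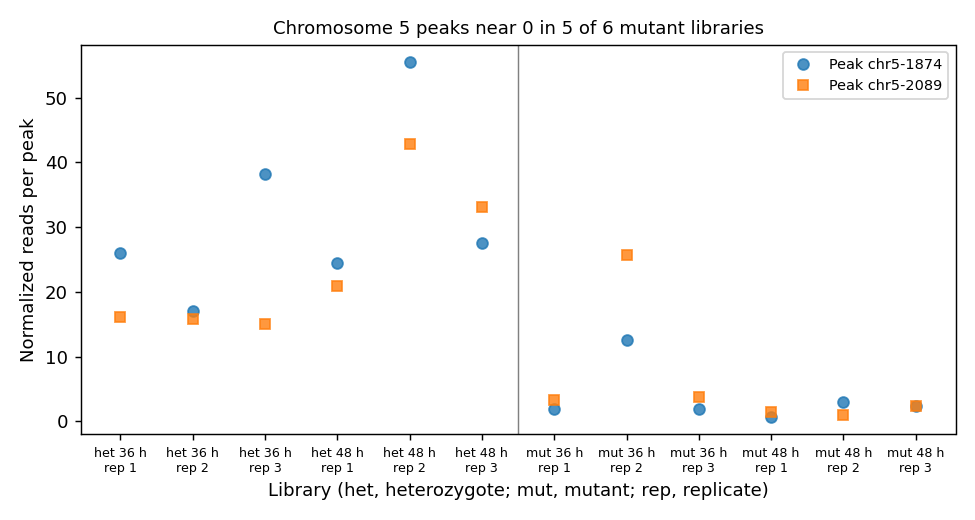
Normalized reads (vertical axis) of the 2 named chromosome 5 peaks in each mouse library (horizontal axis), 1 point per peak and library. Both peaks were under 4 in 5 mutant libraries, while mutant 36 h replicate 2 held 12.6 and 25.7, within or near the heterozygote values.

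The time comparison asked which peaks differed between 36 and 48 h, 12 h apart in a 24 h cycle. In mutants peak chr5-814 on chromosome 5 rose from 17.2 ± 2.87 to 54.1 ± 14.4 normalized reads (SD, n = 3 each), a log2 change of 1.58 (SE 0.240, limma adjusted p = 0.0358). It was the only peak to pass in mutants, with 2530 at an unadjusted p under 0.05 against 2144 expected. In heterozygotes chr5-814 stood at 22 ± 4.11 at 36 h and 41.1 ± 6.26 at 48 h (SD, n = 3 each). No peak passed with limma in heterozygotes, with 3276 at an unadjusted p under 0.05, and none with edgeR or DESeq2 on recovered reads. The smallest p in heterozygotes was at chr11-578 on chromosome 11, with 43.2 ± 10.8 at 36 h and 18.5 ± 1.44 at 48 h (SD, n = 3 each, limma adjusted p = 0.403). Replicate numbers may pair the heterozygote libraries, and with the number as a block 1 peak passed. The call at chr5-814 was lost when any mutant library, heterozygote 36 h replicate 1 or heterozygote 48 h replicate 1 was left out, each giving 0 calls in mutants, and leaving out heterozygote 48 h replicate 2 gave 13. Leaving out heterozygote 48 h replicate 1 gave 12 calls in heterozygotes. In mutants limma on the 6 mutant libraries alone called 425 peaks, edgeR called 22 and DESeq2 called 1. The call at chr5-814 ended, with 0 calls, in limma without the intensity trend, with the covariate, among peaks with a mean of at least 50, and on the 10 libraries with recovered reads. Without both replicate 2 libraries at 36 h limma called 1 peak, a different one.

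The interaction asked whether the change with time differed between genotypes. No peak passed with limma, with 1459 at an unadjusted p under 0.05 where 2144 were expected, and none with edgeR or DESeq2. Changes with time in heterozygotes and in mutants, which share no library, correlated across peaks with r = 0.266. Of 127 peaks with p under 0.001 in mutants, 110 had the same sign in heterozygotes, or 86.6%, and of 81 such peaks in heterozygotes 71 had the same sign in mutants, or 87.7%. Peak chr5-814 was higher at 48 h in both genotypes, and its passing in mutants alone does not show a difference between them.

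The human comparison asked which of 144673 islet peaks followed a 24 h rhythm. The authors' deposited table gave no peak an adjusted p under 0.05, 0.10 or 0.01, and its smallest adjusted p was 0.303. At an unadjusted p under 0.05 it listed 7087 peaks, or 4.90%, where 7234 were expected from uniform p-values. At p under 0.01 it listed 2294 where 1447 were expected. Many low p-values came in coarse steps, with 0.000999 at a peak of RORA and 0.002997 at peaks of PER2 and BHLHE40. All of these had the smallest adjusted p, 0.303. Such steps limit how small an adjusted p can become, so the absence of passing peaks does not show that no peak was rhythmic. The smallest p in the authors' deposited table, 6.27e-06, was at chromosome 5, 89030588 to 89031487 (hg38), where MEF2C is the nearest protein-coding gene at 126483 bp. Peaks within TRMT11 at chromosome 6, 126225455 to 126226276 (p = 1.06e-05), and within PTPRN2 at chromosome 7, 158143270 to 158143975 (p = 2.99e-05), followed in the authors' deposited table. Their best waveforms peaked at 16, 14 and 4 h on a 24 h clock. PTPRN2 encodes a membrane protein of the secretory granules that hold insulin. The 10 smallest p-values also included peaks nearest to TMEM176B, HSPA13, ZFPM2, NDUFB10, SPECC1L, CCDC50 and PRMT3, all at an adjusted p of 0.303.

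**Figure D3:**
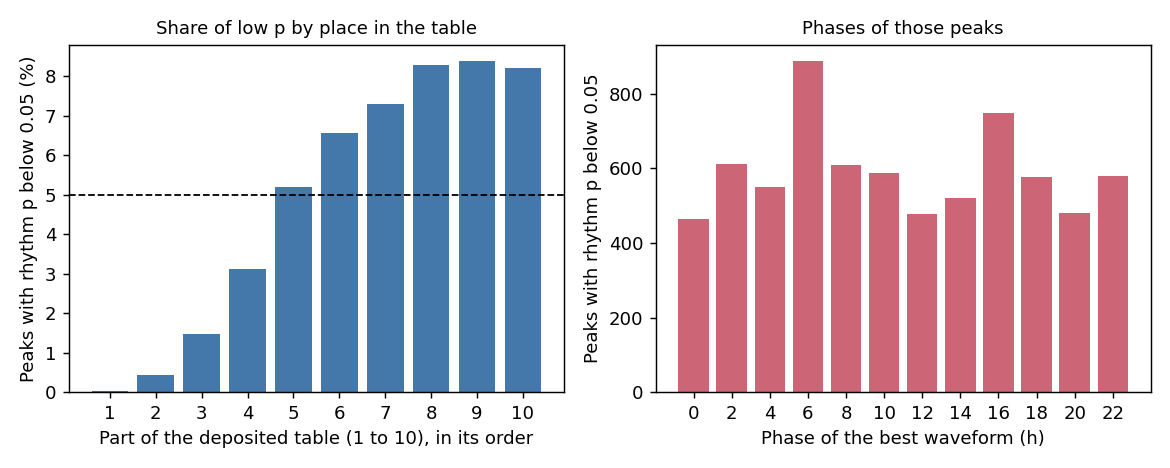
Left, percent of human peaks with an unadjusted rhythm p under 0.05 (vertical axis) in each of 10 equal parts of the authors' deposited table in its own order, with a dashed line at 5%, and right, number of those peaks (vertical axis) by the phase of their best waveform in hours. The share was 0.0415% in part 1 and 8.20% in part 10, and phases of 6 and 16 h held 887 and 747 peaks.

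Of the 22 core clock genes, 8 had a peak with an unadjusted p under 0.05 in the authors' deposited table, 16 of 287 peaks where 13.2 were expected from random peaks matched on place in the table (permutation test, adjusted p = 0.947 over 17 lists). RORA, a receptor that drives BMAL1, had 5 such peaks of 85, with the smallest p of 0.000999 at chromosome 15, 60496937 to 60497849, inside the gene and with a phase of 18 h. PER2, a repressor of the clock loop, had 1 of 16 in the authors' deposited table, inside the gene at chromosome 2, 238283341 to 238284000, with a phase of 6 h. BHLHE40, another clock repressor, had 2 of 12, the lower inside the gene at chromosome 3, 4983750 to 4984602, with a phase of 20 h in the authors' deposited table. NPAS2, RORB, TEF, HLF and NFIL3 had the others, and no peak of BMAL1, CLOCK, PER1, CRY1, CRY2, NR1D1 or DBP had a p under 0.05 in the authors' deposited table. No core clock peak passed when adjusted over the list alone.

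Of the beta cell identity genes 7 had such a peak in the authors' deposited table, 12 of 367 peaks against 13.8 expected (permutation test, adjusted p = 1.00). The smallest p was at PDX1, 0.000333 for a peak at chromosome 13, 27930746 to 27931593, which lies 4433 bp outside the gene and had a phase of 20 h in the authors' deposited table. PAX6, ISL1, GIPR, HNF4A, RFX6 and ABCC8 held the other 11. Of the exocytosis and secretion genes 9 had such a peak, 31 of 526 peaks against 24.5 expected (permutation test, adjusted p = 0.830), and 1 peak, the PTPRN2 peak above, passed when adjusted over the list alone. The calcium channel gene CACNA1D had 10 of 75 peaks, PTPRN2 10 of 137 and CACNA1C 4 of 99 at an unadjusted p under 0.05, and the granule protein genes CHGA, CHGB and SCG3 had 1 each in the authors' deposited table.

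Of the NF-kB pathway and target genes 5 had such a peak, BIRC3, CXCL1, ICAM1, SOD2 and RELB, with 6 of 141 peaks against 6.41 expected from the authors' deposited table (permutation test, adjusted p = 1.00). Of the IL-1 signalling genes only IL1RAP, the accessory protein of the IL-1 receptor, had any, and it held all 5 of the 86 list peaks, against 4.29 expected (adjusted p = 1.00). The lowest lay inside IL1RAP at chromosome 3, 190590851 to 190591741, with a phase of 4 h in the authors' deposited table. No peak of either list passed when adjusted over the list alone.

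Among markers of other islet cell types, alpha cell genes had 11 of 110 peaks at an unadjusted p under 0.05 in the authors' deposited table against 5.17 expected, which missed the threshold (permutation test, p = 0.0244, adjusted p = 0.415). These included peaks of ETV1, GRIA3 and GCG, and the peak of GCG, the glucagon gene, had a phase of 12 h. Within 20 kb alpha cell genes had 6 of 79 peaks against 3.35 expected (permutation test, p = 0.230). Among overlapping peaks they had 4 of 51 against 2.30 (permutation test, p = 0.392). In the authors' deposited table delta and PP cell genes had 6 of 76 peaks against 3.93 expected (adjusted p = 0.830), acinar genes 3 of 48 against 2.45 (adjusted p = 1.00), and ductal genes 2 of 92 against 4.49 (adjusted p = 0.830). Endothelial genes had 2 of 50 against 3.06, macrophage and leukocyte genes 1 of 30 against 1.17, and fibroblast and stellate genes 4 of 61 against 3.29, each with an adjusted p of 1.00 by the permutation test.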

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

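The settings with library quality weights, the covariate of signal in the top 1% of peaks, the 10 libraries with recovered reads, 2 libraries left out, both times of a number averaged, peaks overlapping a gene, the end of the human table and the empirical p were chosen after the data were seen. Named peaks kept their direction in all 1256 values compared over 45 pairs of a peak and a comparison (41 peaks), and of 729 values for the 26 pairs that passed, 174 no longer passed. These peaks were picked for large changes or small p-values in the same libraries, so a kept direction was likely beforehand. The adjusted p of chr9-993 ranged from 5.09e-05 to 0.999 and that of chr5-2089 from 0.00071 to 0.349. The 433 genotype calls over both times stayed within 1.5 times with pseudocounts of 0.5 and 5, no filter, median ratio and cyclic loess scaling. Among peaks with a mean of at least 50, 15 of 5572 were called, a smaller share than the 433 of 42889. The 433 calls became 661 with quantile scaling, 0 without the intensity trend, 703 with the replicate block, 196 with both times of a number averaged (fewer samples), 946 at a threshold of 0.10, 731 with edgeR, 195 with DESeq2, 129 with limma on the same 10 libraries, 1063 with quality weights, 0 with the covariate and 952 without both replicate 2 libraries at 36 h. Leaving out 1 library gave 54 to 1026. For genotype at 36 h the 0 calls became 8 with quantile scaling, 337 with edgeR, 30 with DESeq2, 10 with limma on the same libraries, 412 with quality weights and 84 without those 2 libraries, and 0 to 15 with 1 library left out. For genotype at 48 h the 5 calls became 58 with a pseudocount of 5, 0 with a mean of at least 50, 29 with quantile scaling, 0 without the trend, 82 with the replicate block, 16 with only the groups compared, 129 at 0.10, 2 with DESeq2, 3 with limma on the same 10 libraries, 28 with quality weights, 0 with the covariate, 15 without those 2 libraries, and 0 to 192 with 1 library left out. For time in heterozygotes 0 calls became 1 with the replicate block and 0 to 12 with 1 library left out. For time in mutants the 1 call became 0 with a mean of at least 50, 15 with quantile scaling, 0 without the trend, 3 with the replicate block, 425 with only the groups compared, 22 with edgeR, 0 with limma on the same libraries, 404 with quality weights, 0 with the covariate, and 0 to 13 with 1 library left out. The interaction stayed at 0 calls in each setting run, each library left out included. The causes of these differences were not tested.

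The replicate block left genotype at 36 h and the interaction at 0 calls. In the comparisons of genotype and of time in mutants the libraries share only a number, and 2 of 6 libraries correlated best with their own number for genotype at 36 h, 4 of 6 at 48 h and 2 of 6 for time in mutants. For time in heterozygotes, 6 of 6 did.

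The human count of 0 was the same at thresholds of 0.10 and 0.01. It was also the same among the last 72336 peaks of the table readjusted on their own, where the smallest adjusted p was 0.179. These settings share the stepped p-values, so the repeats add little. The count became 7087 at an unadjusted gamma p of 0.05 and 6272 at an unadjusted empirical p of 0.05. No gene list passed within 20 kb or among overlapping peaks. Ratios of observed to expected counts crossed 1 within 20 kb for acinar (0.971), fibroblast and stellate (0.744), NF-kB (1.14) and cell cycle (1.04) genes, and among overlapping peaks for acinar (0.704), fibroblast and stellate (0.598), NF-kB (1.34) and hypoxia (0.763) genes, and the cause was not tested. GC scaling of mouse peaks, mouse gene lists with an estimated correlation, promoter peaks, motifs, human settings that need values per library, and human peaks by mean level were not run. Heterozygote 48 h replicate 2, with 513207 reads and a median of 8 reads per peak, sets the least precise values.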

Other observations

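The tests of explanations, of splits of the samples, of shared effects and of gene lists at an unadjusted p were chosen after the results were seen. In the authors' deposited table, genes of the hypoxia response had 9 of 146 peaks with an unadjusted p under 0.05 against 6.31 expected, at NDRG1, BHLHE40, SLC2A1, VEGFA, EGLN3, ADM and BNIP3 (permutation test, adjusted p = 0.830). Genes of the unfolded protein response had 9 of 110 against 5.08 expected (permutation test, p = 0.132, adjusted p = 0.830). Within 20 kb they had 7 of 77 against 3.43 (permutation test, p = 0.104). Among peaks overlapping the genes, a setting chosen after the data were seen, they had 7 of 52 against 2.34 (permutation test, p = 0.0162, adjusted p = 0.275). Those include HERPUD1, ERN1 and ATF6, which act in protein folding stress of the endoplasmic reticulum. cAMP and immediate early genes, the targets that forskolin is known to induce, had 19 of 308 against 14.0 expected (adjusted p = 0.830), 10 of them at PDE4D, a cAMP phosphodiesterase. Dedifferentiation and disallowed genes had 5 of 64 against 2.75 (adjusted p = 0.830) and cell cycle genes 1 of 47 against 1.46 (adjusted p = 1.00).

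Among human peaks with an unadjusted p under 0.05 in the authors' deposited table, phases of 6 h (12.5%) and 16 h (10.5%) were the most frequent, and the same phases led among all peaks (11.4% and 13.5%). In the mouse table, the authors' deposited adjusted p was under 0.05 for 393 of the 433 genotype calls, or 90.8%. Its Spearman correlation across peaks was 0.833 with an F test over the 4 groups and 0.687 with the genotype test.

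The real groups gave 433 genotype calls over both times. Because replicate numbers may pair the heterozygote libraries, splits were compared that move both times of a number together. The highest of the 9 others gave 3 calls, and 10 splits are too few for a share under 0.05. Among 100 splits that may break the pairs, the real one included, the highest other gave 558. That split exchanges the replicate 2 libraries of the 2 genotypes at 36 h, which points to a structure of the samples. At 48 h the real split gave 5 calls and the highest of 9 others 1, and in mutants over time 1 and 0. At 36 h the values were 0 and 0, and for time in heterozygotes 0 and 15. These 4 comparisons have 10 splits each, too few for a share under 0.05. The 4 heterozygote splits that part all 3 numbers, the real one included, each gave 0 calls. For the interaction the real count was 0, which each of 100 splits reaches by construction, with a highest of 16, so the splits decide nothing. Effects of genotype at 36 and 48 h correlated at 0.388, with a highest other of 0.279 among 10 splits that keep the numbers together, again too few for a share under 0.05. Effects of time in the 2 genotypes correlated at 0.266, and only the real one of 40 splits that part all heterozygote numbers was as large, with a highest other of 0.232. These splits rest on a pairing found in the same data and were 1 of several unadjusted sets, so they do not exclude chance. Among 100 splits that may break the pairs, 4 were as large, with a highest other of 0.316.

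The first pattern weighed is the set of genotype calls, of which 77 still passed with 10 libraries thinned to 513207 reads each, where depth no longer differed, against 142 in the same libraries scaled without thinning. The lost calls do not decide on depth, since thinning also removes reads. The median log2 change of the 433 peaks was 1.03 in the 10 libraries as deposited and 1.05 after thinning, and all kept their direction. These sizes did not shrink once read numbers were equal in those 10 libraries. They do not decide on unequal depth, because random thinning hardly changes expected ratios of scaled reads and the peaks were called partly there. Nor do they cover the 2 left out or library properties that go with depth. The share of signal in the top 1% of peaks, a sign of library enrichment, differed between genotypes over libraries (p = 0.0195 by an exact permutation test), although mutant 48 h replicates 1 and 3, both at 4.94%, lay within the heterozygote range of 4.81% to 4.99%. With it as a covariate the median change went from 1.10 (median SE 0.235) to 0.885 (median SE 0.376), 0.806 times its value, all 433 kept their direction and 0 passed, because the SE rose and the change shrank. Genotype and this property of the libraries cannot be told apart here, since the measure follows genotype in part. A genotype effect on islet chromatin stays open and untested.

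The second pattern is a set of 4 chromosome 5 peaks, noticed and tested on the same data, with a log2 change of -2.5 or less in a fit without both replicate 2 libraries at 36 h. They held 0 to 4.54 normalized reads in 5 mutant libraries, 6.98 to 55.4 in the 6 heterozygotes, and 8.37 to 25.7 in mutant 36 h replicate 2. An exchange of labels with heterozygote 36 h replicate 2 is argued against at these peaks. That library lay at 0.216 of the way from heterozygote to mutant there, and at 0.446 or less at each peak. Values elsewhere go the other way, so the exchange is not excluded. On other chromosomes the same library lay at 0.844, and the exchanged labels gave 558 genotype calls against 433. A single wrong label on mutant 36 h replicate 2 is argued against by the unplaced sequence JH584304, where it lay at 1.32 and the heterozygote library at -0.0506, but stays open, because mutant 48 h replicate 3 was near heterozygotes there (24.4 beside 32.7) and on other chromosomes both lay alike, at 0.806 and 0.844. A stretch of chromosome 5 that differs in DNA between the mice may also lie behind the set, but this stays open, because the excess of strong losses there (4 of 9 with a log2 change of -2 or less, two-sided Fisher's exact test, p = 0.00155, and 5 of 19 that were 4-fold lower by medians, p = 0.00554) was noticed before it was tested on the same data, and the test over all lower peaks, which dilutes them, did not pass (adjusted p = 0.564).

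The third pattern is that human peaks early in the table rarely had a low rhythm p. The share with p under 0.05 was 0.0415% in part 1 of 10, where 47.2% of peaks hold a gene end, and 8.20% in part 10, where 1.58% do. In part 1, 96.1% of peaks had their lowest value in the same 3 of 24 libraries, against 10.6% in part 10. The 3 libraries that most often held the lowest value and the 3 that most often held the highest were set apart. In parts 1 to 5, peaks with both extremes elsewhere reached p under 0.05 in 4.54% of cases. This lay between the 3.19% of other peaks there, weighted to the same parts, and the 7.85% of peaks in parts 6 to 10 with extremes elsewhere. By part, the share was 0 of 189 peaks in part 1, 1.23% in part 2 and 2.02% in part 3. It was 4.37% in part 4 and 6.06% in part 5, which held 3821 and 5824 of the 12546 peaks. A few libraries that differ in scaling or quality may mask rhythms at early peaks, but this and less rhythm at those peaks cannot be told apart without values per library, and no biological explanation was tested.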
